A study of Homo sapiens with 6 samples.

How the data were processed

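RNA sequencing data of 6 libraries were used, 3 from MDA-MB-231 cells with SRPK2-FLAG and 3 from cells with an empty vector, grouped by their titles. Per the labels' protocols, total RNA was extracted with TRIZOL and DNase treated, and libraries were sequenced in paired-end mode on a NovaSeq system. The series' design text calls the libraries strand-specific and the replicates biological. The submitters' processing notes name bcl2fastq, FastQC and HISAT2 and the build GRCh38, without versions. The read counter, its strand setting and the annotation release are not given in the sources used here, so values of overlapping and antisense genes are uncertain.

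The authors deposited a table of whole-number counts per gene, not normalized, with 29710 genes, and a table of FPKM values with 29256 genes, rounded by the authors to 2 decimals. The 454 genes in the first table alone had at most 8 reads in a library. Gene identifiers were matched without their version to GENCODE 29 (28804 matched) for coordinates, overlaps, transcript length and GC content. The identifiers' versions show that the authors' annotation was another release.

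Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, glmQLFit and glmQLFTest, two-sided). The 16515 tested genes held 99.9% of the reads. Benjamini-Hochberg adjustment covered all tested genes, with a threshold of 0.05, and a size threshold of 2-fold where stated. The fit held only the group as a term. SEs were taken as the absolute log2 fold change over the square root of the F statistic. The biological coefficient of variation was 5.85%. CPM values were TMM scaled. Principal components used log2 CPM with a prior count of 2.

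Before the data were examined, 42 gene lists on splicing, translation, immunity, adhesion, signalling, stress, metabolism, proliferation and other cell types were fixed, along with the design, most alternatives and the rule for named genes. Lists with at least 5 tested members were tested with limma 3.58.1 (camera on log2 CPM with a preset correlation of 0.01, camera with an estimated correlation, and fry), with Benjamini-Hochberg adjustment over the 41 lists. The list of neuronal and embryonic kidney line markers had 4 tested members and was not tested as a set. Of its members, TUBB3, SYP and PAX8 had edgeR log2 fold changes between -0.17 and 0.09.

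The rule named SRPK2, then up to 12 rises and 12 falls by log2 fold change among called protein-coding genes with a mean log2 CPM of at least 1 and groups that did not overlap (57 rises and 8 falls were eligible), then up to 4 called members of each list with the largest absolute change, or the 2 most abundant where a list had none called, and SRPK1, SRPK3 and the SR proteins. Not every gene so named is printed, and the results of a few genes are not reported here.

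Alternatives were RLE size factors, library size alone, no filter on low counts, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, limma on log2 of the deposited FPKM plus 1 or 0.1 (mean FPKM of at least 0.5, or no filter), the replicate number as a block, a loess correction of each library for gene length (span 0.3, length from reads and FPKM, 15809 genes) with and without that block, and leaving out each library. Corrections for GC content (16331 genes) and principal transcript length were added after the data were seen. The scripts were tested on simulated counts for this comparison over 16323 genes, with 200 genes changed and all tested mitosis genes raised 1.25-fold. Of 50 genes per size, 50% changed 1.25-fold, 74% changed 1.5-fold, 86% changed 2-fold and 100% changed 4-fold were called. Outside both sets, 15 unchanged genes were called. The simulated genes varied independently, with no trend shared across a library, so these shares may not hold for the real libraries. Python 3.11.15 and matplotlib 3.10.9 were used for figures.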

Results

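The study measured gene expression in MDA-MB-231 cells, a triple-negative breast cancer line, by strand-specific paired-end RNA sequencing. SRPK2 is a kinase that phosphorylates serine- and arginine-rich (SR) splicing factors. Cells overexpressing FLAG-tagged SRPK2 (3 biological replicates) were compared with cells carrying an empty vector (3 biological replicates), to ask which transcripts differ when SRPK2 is raised. The control libraries held 35698295, 33590410 and 36225361 reads assigned to genes, and the SRPK2 libraries 31140537, 35262735 and 36908878. Between 23664 and 24453 genes had at least 1 read in a library. Mitochondrial genes took 9.33% to 10.4% of the reads. Replicates of a group differed by more than sampling noise, with a chi-square of 4.78 to 16.7 per degree of freedom, so no pair was treated as copies of 1 library. On the first principal component of the 500 most variable genes, which held 29.6% of the variance, all 3 control libraries lay below 0 and all 3 SRPK2 libraries above it. Over all tested genes it held 33.9%, and SRPK2 replicate 2 lay at 0.25, close to control replicate 3 at -3.91.

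SRPK2 mRNA was 6.52-fold higher in the SRPK2 libraries. Its level was 38.6 ± 2.27 CPM (SD, n = 3), a read count scaled to library size, with the empty vector and 252 ± 41.0 CPM (SD, n = 3) with SRPK2. The log2 fold change was 2.71 (SE 0.10, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.94e-08). In the deposited FPKM values the means were 5.43 ± 0.42 and 36.4 ± 6.61 (SD, n = 3 each). An exact two-sided permutation test of the log2 CPM values gave p = 0.1, the smallest that 3 against 3 libraries allow. SRPK2 (ENSG00000135250.17) lies on chromosome 7 from 105110704 to 105399308 on the minus strand (GRCh38, GENCODE 29). Gene totals do not separate transcripts of the construct from those of the endogenous locus.

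**Figure D1:**
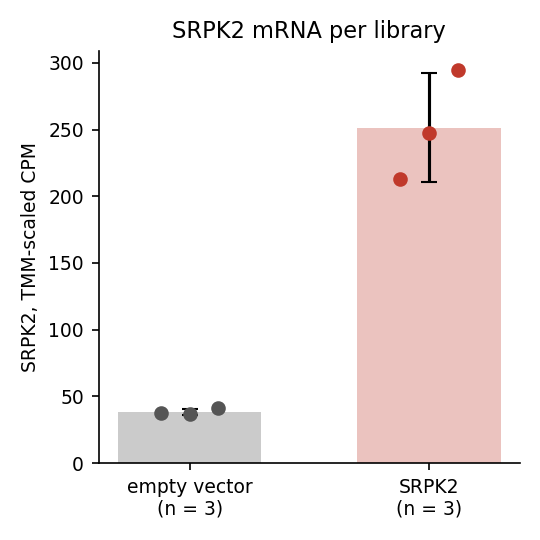
SRPK2 level in each library in TMM-scaled CPM (vertical axis, from 0), for the empty vector and the SRPK2 libraries (n = 3 each). Bars are means, error bars are SD and points are libraries, and the control libraries lie between 36.7 and 41.1 CPM while the SRPK2 libraries lie between 213 and 294 CPM.

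The related kinase SRPK1 had a log2 fold change of 0.05 (SE 0.05, edgeR adjusted p = 0.662). SRPK3 had at most 8 reads in a library and was not tested. Of the 13 tested SR protein genes, the substrates of these kinases and their close relatives, 0 passed the threshold in the edgeR test, and 0 did when adjusted over the list alone. SRSF7 had the largest absolute log2 fold change of the list, at -0.14 (SE 0.06, edgeR adjusted p = 0.247), and SRSF3, the most abundant member, had -0.11 (SE 0.05, adjusted p = 0.291). SRSF1, SRSF2, SRSF4, SRSF5, SRSF6, SRSF8, SRSF9, SRSF10, SRSF11, TRA2A and TRA2B had values between -0.12 and 0.11, and SRSF12 had too few reads to be tested. The list's median was -0.06 (camera adjusted p = 0.144). Core spliceosome genes had a median of -0.02, with 0 of 44 past the threshold (camera adjusted p = 0.214), and nonsense-mediated decay factors one of 0.06, with 0 of 11 (camera adjusted p = 0.531). The core spliceosome median was 0.01 when libraries were scaled by size alone. Gene counts carry no information on exon usage, so the splicing of these or other transcripts was not measured.

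Across the transcriptome 63 genes rose and 12 fell in the edgeR test, 75 of 16515 tested at an adjusted p under 0.05. Of these, 66 were protein coding and 8 were lncRNAs. Most changes were small. Apart from SRPK2 the median absolute log2 fold change of the called genes was 0.43, and 6 genes changed at least 2-fold. Besides SRPK2 these were IFNL1, EIF3FP3, RP11-297P16.4 and RP1-127C7.8, which rose, and LCN2, which fell. Apart from SRPK2 and LCN2, they lay outside the rule for named genes and are given after their values were seen. EIF3FP3 is a processed pseudogene whose reads can be shared with its parent gene. IFNL1 and EIF3FP3 missed the threshold without control replicate 1 or 3 or SRPK2 replicate 1 (edgeR adjusted p between 0.0662 and 0.124), and RP11-297P16.4 when any 1 library other than SRPK2 replicate 2 was left out (0.0508 to 0.161). Over all tested genes the groups did not overlap for 20.1%, where chance gives 10%. At an unadjusted p under 0.05 there were 2833 genes, where chance gives about 826. These excesses cannot be read as numbers of genes changed by SRPK2. A split of the libraries that mixes the groups (control replicates 1 and 2 with SRPK2 replicate 2, against the rest) called 319 genes in the same test. The number of called genes depended strongly on single libraries. It was 27, 46 and 33 without control replicate 1, 2 or 3, 43 and 42 without SRPK2 replicate 1 or 3, and 1403 (551 higher, 852 lower) without SRPK2 replicate 2. With no filter on low counts it was 997 (390 higher, 607 lower).

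**Figure D2:**
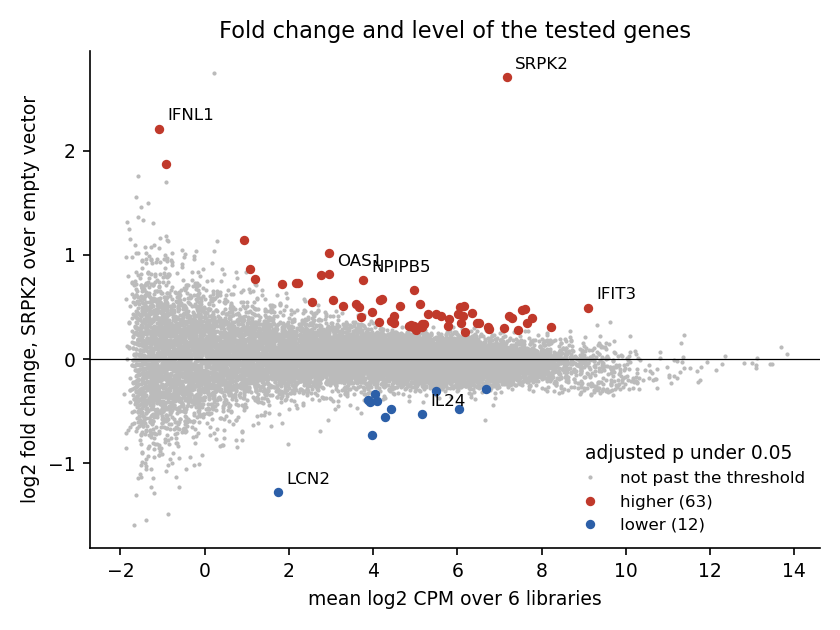
Log2 fold change of SRPK2 over empty vector (vertical axis) against mean log2 CPM over the 6 libraries (horizontal axis) for the 16515 tested genes, with one point per gene. Red points mark the 63 genes called higher and blue points the 12 called lower, and SRPK2 stands at 2.71 while most other called genes lie within 1 of zero.

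The largest rises among called protein-coding genes included 3 members of the fixed list of interferon-stimulated genes (OAS1, RSAD2 and XAF1) and 3 of the list of inflammatory cytokines (CXCL10, CCL5 and CXCL11). The antiviral enzyme OAS1 rose 1.76-fold (log2 fold change 0.81, SE 0.09), and CX3CL1, a membrane-bound chemokine, 1.74-fold (0.80, SE 0.10). TNFRSF9, a costimulatory receptor, rose by 0.77 on the log2 scale, and its levels of 1.65 and 2.81 CPM were low. The chemokines CXCL10, CCL5 and CXCL11 rose by 0.73, 0.72 and 0.56, the guanylate-binding protein gene GBP4 by 0.66, RSAD2 by 0.58, XAF1 by 0.56 and the cytokine TNFSF15 by 0.55. NPIPB5 rose by 0.76, but it belongs to a family of near-identical copies whose reads the counting could split, so its value is uncertain. The edgeR adjusted p of these genes lay between 0.00167 and 0.0490. TNFRSF9, CCL5 and TNFSF15 missed the threshold when any 1 library other than SRPK2 replicate 2 was left out (edgeR adjusted p between 0.0508 and 0.229), CXCL10 without control replicate 1 or 3 or SRPK2 replicate 1 (0.109 to 0.198), CXCL11 without control replicate 1 or 3 (0.0887 and 0.124) and RSAD2 without control replicate 1 (0.0604). CCL5 also missed it with RLE size factors (edgeR adjusted p = 0.0513).

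Interferon-stimulated genes were the group with the clearest change. Of 40 tested members 18 rose and 0 fell, and 33 rose when adjusted over the list alone. The median log2 fold change was 0.39, and 37 of the 40 values were positive. OAS1, RSAD2 and XAF1 rose as given above, and MX1, a dynamin-like antiviral GTPase, rose 1.44-fold (0.52, SE 0.07, edgeR adjusted p = 0.00357). Among the more abundant members IFIT3 rose from 460 to 648 CPM (0.49, SE 0.05) and IFIT2 from 163 to 227 CPM (0.48, SE 0.05), both with an edgeR adjusted p of 0.00167. ISG15, IFI27, BST2 and IFI35 did not pass, with log2 fold changes between -0.07 and 0.07. The groups did not overlap for 31 of the 40 genes, where chance gives 10% and the share over all tested genes was 20.1%. The list passed camera with a preset correlation (adjusted p = 1.48e-23) and the directional fry test (adjusted p = 0.00311). The camera call was lost with adjusted p = 0.14 with an estimated correlation.

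**Figure D3:**
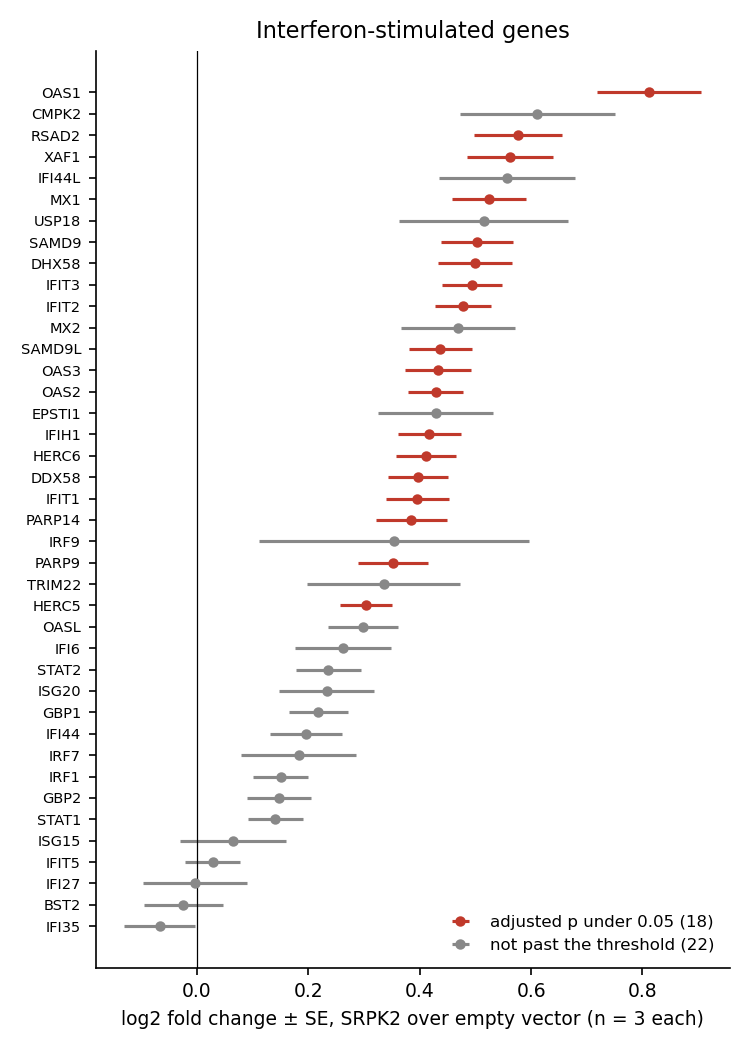
Log2 fold change with SE (horizontal axis, SRPK2 over empty vector, n = 3 each) for the 40 tested interferon-stimulated genes, one per line. Red points mark the 18 genes past the adjusted p threshold and grey points the 22 that were not, and 37 of the points lie above 0.

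Inflammatory cytokines and targets of NF-kB, a transcription factor of inflammation, moved in both directions. Of 31 tested members 8 rose and 2 fell, and adjusted over the list alone 13 rose and 4 fell. CXCL10, CCL5 and CXCL11 were among those that rose, as was BIRC3, an inhibitor of apoptosis (0.34, SE 0.06, edgeR adjusted p = 0.0224). IL24, a cytokine gene, fell by 0.53 (SE 0.06, edgeR adjusted p = 0.00234), and PTGS2, the inducible cyclooxygenase, fell by 0.41 (SE 0.07, edgeR adjusted p = 0.0297). The list's median was 0.11 (camera adjusted p = 0.0145, and adjusted p = 0.691 with an estimated correlation). BIRC3 missed the threshold without control replicate 1 or 2 or SRPK2 replicate 3 (edgeR adjusted p 0.0586 to 0.181), and the list without control replicate 3 or SRPK2 replicate 2 (camera adjusted p = 0.118 to 0.135). Antigen presentation genes did not pass, with 0 of 22 past the threshold (1 rose and 5 fell adjusted over the list alone), a median of -0.03 and a camera adjusted p of 0.364. The most abundant, B2M, had a log2 fold change of -0.03. The list's median was 0.00 when libraries were scaled by size alone.

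LCN2, an iron-sequestering lipocalin, had the largest fall, from 4.68 ± 0.64 to 1.95 ± 0.47 CPM (SD, n = 3 each; log2 fold change -1.28, SE 0.17, edgeR adjusted p = 0.00372). PMEPA1, a TGF-beta-induced gene, fell by 0.48 (SE 0.06, edgeR adjusted p = 0.00372). INHBA, which encodes an activin subunit, fell by 0.34, and FST, which encodes the activin-binding protein follistatin, fell by 0.29. HS3ST3B1, a heparan sulfate sulfotransferase gene, fell by 0.39 and SHISA2 by 0.30. The edgeR adjusted p of these last 4 genes lay between 0.0269 and 0.0480. With libraries scaled by size alone PTGS2, HS3ST3B1, INHBA, SHISA2 and FST no longer passed (edgeR adjusted p between 0.0508 and 0.0792). HS3ST3B1, INHBA and FST also missed the threshold when any 1 library other than SRPK2 replicate 2 was left out, and PTGS2 and SHISA2 without control replicate 1 or 3 or SRPK2 replicate 1 or 3 (edgeR adjusted p between 0.0523 and 0.245). PMEPA1 was the only one of 20 tested TGF-beta target genes past the threshold, while 2 fell adjusted over the list alone, and the list had a median of 0.03 (camera adjusted p = 0.764).

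Few collagen and extracellular matrix genes passed the threshold. COL6A1, a collagen VI chain, rose by 0.35 (SE 0.07, edgeR adjusted p = 0.0480) and LAMB2, a laminin chain, by 0.29 (SE 0.05, edgeR adjusted p = 0.0461). These were 2 of 32 tested members, and 19 rose adjusted over the list alone. The median was 0.17 (camera adjusted p = 3.40e-08, adjusted p = 0.691 with an estimated correlation, and fry adjusted p = 0.173), and it was 0.11 after a correction of each library for gene length and 0.10 after one for principal transcript length. The matrix list still passed after each (camera adjusted p = 1.89e-06 and 1.71e-06), but not with an estimated correlation (0.654 and 0.690). Among integrins and matrix proteases ITGB4, an integrin chain of hemidesmosomes, rose by 0.35 (SE 0.07, edgeR adjusted p = 0.0480), 1 of 27 members, while 5 rose and 1 fell adjusted over the list alone. That list's median was 0.08 (camera adjusted p = 0.0145, and adjusted p = 0.691 with an estimated correlation). Fibroblast markers had a median of 0.21 over 6 tested genes, with 0 past the threshold and 2 that rose adjusted over the list alone (camera adjusted p = 0.0363, and 0.691 as adjusted p with an estimated correlation). COL1A1 and LUM, the most abundant of these, also belong to the matrix list and stood at 3.66 and 2.45 CPM in the controls. Their log2 fold changes were 0.35 (SE 0.12) and 0.52 (SE 0.13), with edgeR adjusted p of 0.203 and 0.113. COL6A1, LAMB2 and ITGB4 missed the threshold when any 1 library other than SRPK2 replicate 2 was left out (edgeR adjusted p between 0.0698 and 0.209), and ITGB4 with RLE size factors (0.0515). The integrin list missed it without control replicate 2 or SRPK2 replicate 3 (camera adjusted p between 0.0599 and 0.173) and the fibroblast markers without control replicate 1 or 3 or SRPK2 replicate 3 (0.0798 to 0.0993). After the gene length and transcript length corrections the integrin list had a median of 0.04 and was past the threshold with neither (camera adjusted p = 0.0595 and 0.0548), and the fibroblast markers missed it after the latter (0.0603).

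Ribosomal protein genes had small negative values throughout, but no single gene passed. All 76 tested members had a log2 fold change below 0, with a median of -0.27, and 0 fell over all genes or adjusted over the list alone. RPLP0 had -0.23 (SE 0.09, edgeR adjusted p = 0.227) and RPS18 -0.27 (SE 0.11, edgeR adjusted p = 0.237). Nuclear oxidative phosphorylation genes had a median of -0.21, with 72 of 73 values negative and 0 past the threshold either way, and ATP5F1B had -0.09 (SE 0.06). That median was -0.15 after the gene length correction and -0.13 after the transcript length correction. The oxidative phosphorylation list still passed after each (camera adjusted p = 1.24e-10 and 3.43e-09), but not with an estimated correlation (0.678 and 0.708). Uncorrected, the ribosomal protein and oxidative phosphorylation lists both passed camera with a preset correlation (adjusted p = 1.19e-14 and 2.02e-11), and each had adjusted p = 0.691 with an estimated correlation. The list medians of single libraries overlapped between the groups. For ribosomal proteins, as deviations from each gene's mean, these were 0.11, 0.33 and -0.03 in the controls and -0.15, 0.10 and -0.36 in the SRPK2 libraries (exact permutation p = 0.2).

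MYC target genes had a median of -0.12, with 0 of 29 past the threshold and 8 that fell adjusted over the list alone (camera adjusted p = 8.84e-07, and adjusted p = 0.691 with an estimated correlation). NPM1, a nucleolar protein gene of that list, had -0.19 (SE 0.07), further from 0 than the list's median, while 4 of the 29 values were positive. ABC drug transporters (median 0.09, 0 of 10), heat shock genes (-0.05, 0 of 18) and hnRNP proteins (-0.04, 0 of 27) also passed camera, with adjusted p of 0.0363, 0.0471 and 0.04997, and had 0 members past the threshold adjusted over the list alone. Each had adjusted p = 0.691 with an estimated correlation. The SRPK and CLK kinases passed as well (median 0.04, camera adjusted p = 0.0471, and adjusted p = 0.691 with an estimated correlation), but SRPK2 itself was the only one of 10 members that rose over all genes, and 2 rose adjusted over the list alone. The mean of that list was 0.32, far above its median, and it was not tested without the overexpressed gene. With libraries scaled by size alone the ABC transporter, heat shock and hnRNP lists missed the threshold (camera adjusted p = 0.0570, 0.179 and 0.281). After the gene length correction the ABC transporter, heat shock and kinase lists missed it (camera adjusted p = 0.146, 0.0872 and 0.285), with medians of 0.03, -0.05 and 0.03, while the hnRNP median was -0.07. After the transcript length correction the ABC transporters (median 0.02) and the kinases missed it (camera adjusted p = 0.269 and 0.104). The hnRNP list missed it when any 1 of the 6 libraries was left out, heat shock genes when any but SRPK2 replicate 2 was, ABC transporters without control replicate 2 or 3 or SRPK2 replicate 1 or 3, and the kinases without control replicate 1 or 3 or SRPK2 replicate 3 (camera adjusted p between 0.0530 and 0.233).

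**Figure D4:**
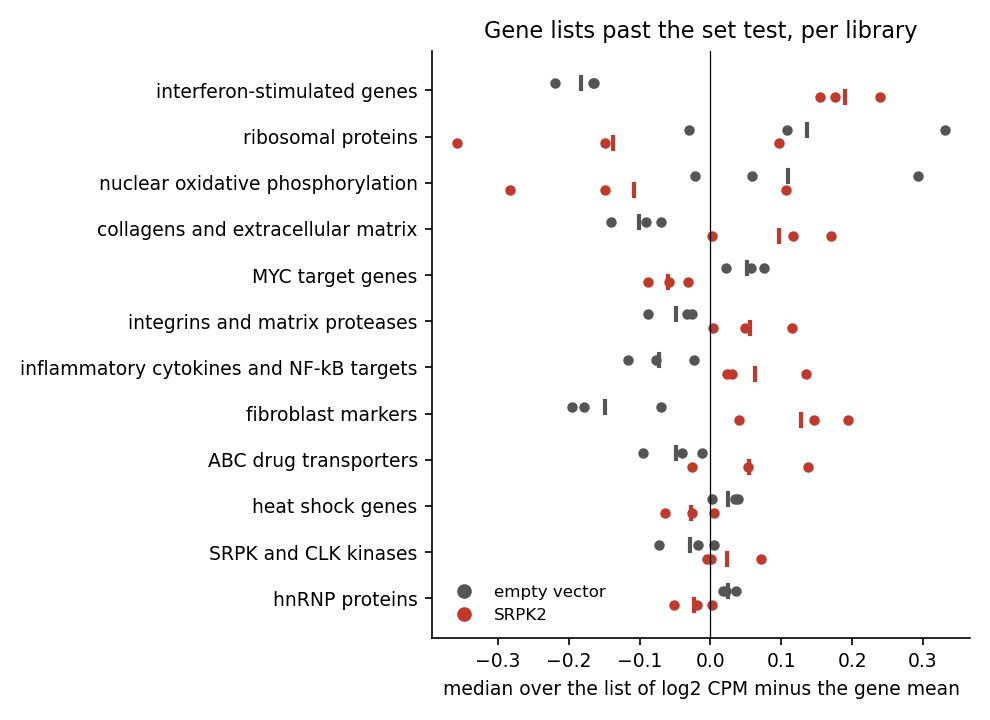
Median over each list of log2 CPM minus the gene's mean over the 6 libraries (horizontal axis), for the 12 lists past camera with a preset correlation. Points are libraries (n = 3 each) and ticks are group means. The groups stand apart for interferon-stimulated genes (from -0.22 to -0.16 in controls and from 0.15 to 0.24 with SRPK2). They also stand apart, by less, for collagens (from -0.14 to -0.07 against 0.00 to 0.17), MYC targets, integrins, inflammatory cytokines, fibroblast markers and hnRNP proteins. They overlap for ribosomal proteins, oxidative phosphorylation, ABC transporters, heat shock genes and the SRPK and CLK kinases.

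The remaining 29 of the 41 lists with at least 5 tested members did not pass camera, with adjusted p between 0.0715 and 0.989 and medians between -0.10 and 0.24. Mitosis genes had a median of 0.02 and E2F targets -0.04, with 0 of 44 members past the threshold in each. Mesenchymal genes (median 0.01, 0 of 20) included VIM at -0.08 (SE 0.06), and epithelial genes (0.05, 0 of 19) included KRT8 at 0.05 (SE 0.06). Targets of p53, NRF2 and Wnt signalling had medians of 0.01, 0.00 and 0.01, again with 0 members past the threshold. KLF4, a transcription factor among the immediate early genes, rose by 0.26 (SE 0.05, edgeR adjusted p = 0.0467), 1 of 28 members, while 1 rose and 4 fell adjusted over the list alone. KLF4 missed the threshold with RLE size factors (edgeR adjusted p = 0.0513). Of markers of other cell types, leukocyte genes had a median of -0.10 (0 of 6 past the threshold), endothelial genes 0.01 (1 of 5) and basal keratin genes 0.24 (0 of 5). The endothelial marker that rose was ROBO4, a guidance receptor (0.32, SE 0.06, edgeR adjusted p = 0.0341). KLF4 and ROBO4 missed the threshold when any 1 library other than SRPK2 replicate 2 was left out (edgeR adjusted p between 0.0599 and 0.191). In 9 of the 41 lists the median, the mean and the camera direction differed in sign.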

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

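Corrections for GC content and principal transcript length, and the counts of interferon-stimulated genes under every setting, were chosen only after results were seen. The SRPK2 level, as a log2 fold change, stayed between 2.53 and 2.81 and past the threshold under every setting run. The 75 called genes became 997 with no low-count filter (40 at least 2-fold, in place of 6), 153 with DESeq2, 121 after the gene length correction, 175 after the transcript length correction and 18 with unfiltered FPKM, and ranged from 27 to 1403 with 1 library left out (2-fold genes 3 to 32). Without SRPK2 replicate 2 there were 1403, and all 75 were among them. A mean CPM of at least 5 left 2 genes at least 2-fold, in part because it tested fewer genes (11088), and FPKM with pseudocount 1 left 1, with or without the filter. The 18 interferon-stimulated genes became 3 with unfiltered FPKM and ranged from 12 to 24 with 1 library left out. In place of 12 lists past camera, 7 were past with no low-count filter and 6 to 11 with 1 library left out (6 to 10 of them among the 12). With an estimated correlation 0 were past, and with fry 1 was. The interferon list (median 0.39) had a camera adjusted p of 0.14 with an estimated correlation, against at most 0.00311 under settings without one. With that correlation it was 0.0907 after the gene length correction and 0.0986 after the transcript length correction. The gene length and transcript length corrections each left 8 of the 12 past. The replicate block gave 3899 called genes, 49 at least 2-fold and 32 interferon-stimulated genes, and with the length correction 3072, 52 and 32. Replicate numbers are shared between groups. After each gene's group mean was removed, same-number correlations were 0.08, 0.23 and 0.17, the first under 0.1, so the numbers were not taken as pairs. By that measure every library correlated best with its own number in the other group, a hint from the data and not the design. Without that removal, control replicates 1 and 3 correlated more with SRPK2 replicate 2 than with their own number. Of 27 named called genes, 9, 15 and 11 passed without control replicate 1, 2 or 3, and 12, 27 and 13 without SRPK2 replicate 1, 2 or 3. Filtered FPKM lost 13 of 25 with either pseudocount and unfiltered FPKM all 27, while the GC correction lost 6, limma-voom 5, library size alone 5, RLE 3 and a mean CPM of at least 5 lost 5 of 22. No named gene or list reversed while called. Except where stated, the cause was not tested. At this depth genes with few reads, such as IFNL1, are measured loosely.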

Other observations

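The count of other splits for all called genes, the GC and transcript length corrections, the GC correction of the other split, the expression-matched random sets, the part of the ribosomal protein difference that each correction removed, and the margin of 1 SE around each bound were tests or rules chosen only after results were seen. Of the 75 called genes, 40 were in none of the fixed lists, and those named here were picked after their values were seen. ZC3HAV1, an antiviral protein that binds viral RNA, rose by 0.47 on the log2 scale (SE 0.05), the helicase gene DDX60 by 0.51 (SE 0.06) and STING1, an adaptor of cytosolic DNA sensing, by 0.31 (SE 0.06). IL7R rose by 0.35 (SE 0.05), the Wnt receptor gene FZD4 by 0.51 (SE 0.06) and RAVER1, an RNA-binding protein gene, by 0.51 (SE 0.09). Their edgeR adjusted p lay between 0.00188 and 0.0328. With 1 library left out, STING1 missed the threshold except without SRPK2 replicate 2, RAVER1 missed it without any 1 control or SRPK2 replicate 3, and IL7R without control replicate 1 (edgeR adjusted p between 0.0590 and 0.170).

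IFNL1, a type III interferon gene picked after its values were seen, rose from few reads. It had 5, 7 and 3 reads in the controls and 22, 25 and 24 in the SRPK2 libraries (log2 fold change 2.21, SE 0.35, edgeR adjusted p = 0.0147), and missed the threshold without control replicate 1 or 3 or SRPK2 replicate 1 (adjusted p between 0.0662 and 0.119). IFNL2 had 2, 0 and 0 against 6, 3 and 8 reads and IFNL3 3, 1 and 0 against 5, 3 and 6. These near-identical genes can share reads, and both fell below the filter and were not tested.

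Technical trends were weighed for the rise of interferon-stimulated genes. Their median log2 fold change of 0.39 was 0.35 after the gene length correction, 0.37 after the transcript length correction, 0.38 after the GC correction and at least 0.34 with any 1 library left out, with SEs of 0.02 to 0.03 and all above the bound of 0.20 set for them, which argues against these trends or a single library as the whole cause. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one itself, reached its 18 called interferon-stimulated genes (highest other 1). Likewise only that 1 reached its 6 genes at least 2-fold (highest other 2) and its 12 lists past camera (highest other 7). These counts favour the real split in advance. The interferon list was followed because it stood out there, and the 6 genes and the kinase list among the 12 include SRPK2 itself. Besides, 10 splits are too few for a share under 0.05. A response of the cells to raised SRPK2 may account for the rise, and so may a difference in the delivery or nucleic acid of the vectors, and the design does not separate these.

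The lower ribosomal protein genes were weighed with a structure of the samples, since 2 of 10 splits, the real one included, gave at least the real 75 called genes (control replicates 1 and 2 with SRPK2 replicate 2, set against the rest, gave 319, with a ribosomal protein median of -0.36 against -0.27 in the real split), and 10 splits are too few for a share under 0.05. These libraries have the lowest slopes of log2 level on gene length, from -0.03 to -0.01 per doubling, against 0.00 to 0.05 in the others, and their GC slopes overlap. After the gene length correction that split called 0 genes, as a length trend between libraries would give, but after the GC correction it also called 0, so neither trend is ruled out for that split and the length test is not specific. The ribosomal protein median of -0.27 was -0.23 after the gene length correction, -0.19 after the transcript length correction, -0.27 after the GC correction and -0.16 at its closest to 0 with 1 library left out, all beyond the bound of -0.15 but by less than their SEs of 0.11 to 0.18. For the median to reach the bound of -0.10 set for a trend as the cause, a correction had to remove -0.17 of the -0.27. The GC correction removed 0.00 (SE 0.01), which argues against that trend as the whole cause. The gene length correction removed -0.04 (SE 0.03) and the transcript length correction -0.08 (SE 0.06, a narrower margin). Library by library, however, the ribosomal protein medians fell in the order in which the gene length slopes rose. The ends were control replicate 2 (slope -0.03, median deviation 0.33) and SRPK2 replicate 3 (0.05 and -0.36). A length-linked difference between libraries that the corrections did not remove, a single library and an effect of SRPK2 therefore cannot be told apart.

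The 4 lncRNAs that fell, RP11-161H23.5, AC010761.8, RP11-138I1.4 and RP11-290D2.6, lie opposite TUBA1C, RPL23A, UBB and TPT1 in GENCODE 29, which had log2 fold changes of -0.13, -0.29, -0.14 and -0.20 (SE 0.06, 0.10, 0.08 and 0.08), none past the threshold (edgeR adjusted p between 0.196 and 0.354). RP11-161H23.5 missed the threshold without control replicate 1, AC010761.8 and RP11-138I1.4 without control replicate 1 or 3 or SRPK2 replicate 3, and RP11-290D2.6 except without SRPK2 replicate 2 (edgeR adjusted p between 0.0626 and 0.266). Reads from the abundant partner placed on the other strand could produce such a pattern. The 763 other tested genes opposite a gene at least 50 times as abundant, as holds for 2 of the 4, had a median log2 fold change of -0.087, against 0.03 in random sets matched on expression (SD 0.01, and 0% of 10000 sets as low), while the median of the partners of those 763 was -0.01. That lies between the bounds of -0.15 and -0.05 set for the test, so a change in opposite-strand reads and a change in the lncRNAs cannot be told apart, and no biological explanation was tested.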
